A study of Rattus norvegicus with 12 samples.

How the data were processed

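Total RNA of NRK-52E cells, a rat renal tubular epithelial line, was sequenced in 12 libraries, 3 in each of 4 groups (control, TGF-beta1, TGF-beta1 with 2D-EVs, TGF-beta1 with 3D-EVs). Per the labels, RNA was extracted with TRIzol and treated with DNase I, and libraries were made with a Yeasen Hieff kit. Per the labels TGF-beta1 was given at 10 µg/ml (the unit is in doubt) for 24 h and EVs at 500000000 particles/ml for 48 h. The cells that made the EVs, whether TGF-beta1 stayed in the medium, and when control and TGF-beta1 cells were harvested are not given in the sources used here. Per the submitters' processing notes the tools were fastp, HISAT2, StringTie and DESeq2 with the rat build mRatBN7.2. Their versions, the counting settings, the strand handling and the annotation release are not given in the sources used here. The deposited values are counts per gene, whole numbers made by the authors without normalization, for 24660 genes in 12 libraries. The 12 tables per library were checked and were identical to the joint table, and 0 columns were left unused. The value 1 filled 1514 cells and the value 2 5687 cells, so the smallest counts do not follow plain counting of single reads, and the interval of a count covers counting error only. Genes are named by the symbols in the deposited tables. Of the 24660 names, 16794 matched a RefSeq table of 47357 rat genes on another build (GRCr8), which was used for names and gene order and gave no coordinates. A further 3258 names were Ensembl identifiers and 1631 were assembled transcripts without a gene name, 998 of which were tested and counted but not named.

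Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of the 24660 genes, 5394 were at 0 in every library, and 14184 were kept by filterByExpr with the groups and a minimum count of 10. All 12 libraries entered a single fit of group means with TMM factors (0.983 to 1.03), and 6 contrasts were tested with the quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, with a threshold of 0.05. CPM are TMM-scaled. Within groups, the 12 pairs of libraries differed by 6.82 to 10.9 times the counting variance (chi-square per degree of freedom). Averaged over genes, the spread between libraries was thus above counting error. This average does not show that depth is negligible for weakly expressed genes. Libraries with the same number in different groups were checked for pairing: residuals of the 18 such pairs correlated by -0.067 to 0.045, 0 of them above 0.1, and 5 of 12 libraries correlated best with their own number, so the numbers were not used to pair samples. No sequencing batch is given in the labels, and no library was left out.

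The 21 response lists and 8 marker lists, the named-gene rule, the tests and the alternatives were fixed before the data were examined. The response lists were extracellular matrix, TGF-beta targets and feedback, mesenchymal and contractile, epithelial junctions and keratins, renal tubule function, tubular injury, inflammation and NF-kB, interferon response, cell cycle, p53 with arrest and senescence, NRF2 and oxidative stress, unfolded protein and ATF4 response, heat shock, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, YAP and mechanical targets, lysosome and endocytosis, apoptosis and cell death, and immediate early. The marker lists were fibroblast and pericyte, mesenchymal stromal cell as a possible vesicle source, immune, endothelial, podocyte, erythroid, mitochondrially encoded and ribosomal protein genes. Each list was tested with camera at a preset correlation of 0.01, adjusted over the response lists or over the marker lists of a comparison, and again with an estimated correlation and with fry. Lists with fewer than 3 tested members had no list test. Genes were also adjusted over the list alone. Named genes were, per comparison, the 8 largest rises and 8 largest falls with adjusted p below 0.05, a mean of at least 1 CPM, no overlap between the libraries of the 2 groups and a symbol that is no placeholder. To these came the panel Acta2, Col1a1, Fn1, Vim, Cdh1, Ccn2, Tgfb1, Havcr1 and Lcn2, up to 4 members per list with the smallest p (2 that rose and 2 that fell, or 2 given as values), and up to 5 raised and 5 lowered genes moved back per EV preparation; some were left out from the lower end of a ranking, and a few genes that the rule names are not reported here. Genes outside the rule were named after their values were seen: Thbs1, Cald1, F2r and Edn1 with 2D-EVs, Ctsl, B2m, Csf1 and Icam1 among the DESeq2 calls, genes without counts, and genes that vary within a group.

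Because the comparisons with TGF-beta1 cells share 3 libraries, 50 data sets were simulated with EV libraries drawn from the TGF-beta1 means (negative binomial, fitted dispersions, genes independent) and set beside the numbers of genes moved back, the shares of opposite sign and the correlation of the EV responses. The simulated TGF-beta1 score was 1.01 where the observed was 0.790, so these baselines are approximate. With 3 libraries the TGF-beta1 group could not be divided between the comparisons. The procedure was tested on simulated data with 200 changed genes in each of 10 draws: in 2D-EV against TGF-beta1 cells it recovered 23.6% of 1.2-fold, 67.4% of 1.5-fold, 80% of 2-fold and 86.6% of 3-fold changes, with 6.05% false calls, and in 3D-EV against TGF-beta1 cells 27.6%, 64.4%, 77.8% and 89.2%, with 4.88% false calls. The Benjamini-Hochberg threshold is looser where many genes change. Recovery may therefore be lower in the real comparisons of 2D-EV and 3D-EV with TGF-beta1 cells, where 4 and 0 genes were called. Camera called 20 of 20 simulated sets of 30 genes shifted 1.2-fold, and 2 of 20 unshifted sets. The genes of these sets were drawn independently, so this does not cover lists whose genes vary together or shift by less. The alternatives were DESeq2 size factors in edgeR, no filter on low counts, a stricter filter (at least 10 counts in every library of a group and a mean of at least 1 CPM), DESeq2 1.42.0, limma-voom 3.58.1, a block on the replicate number, the 6 libraries of a comparison alone, an absolute log2 fold change of at least 1, leaving out each library, fry and an estimated correlation. After the data were seen, libraries thinned to the smallest total and a fit without genes that vary over 5-fold within a group (CPM plus 0.5) were added. Raw reads were not used here.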

Results

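Gene expression was measured by RNA sequencing in NRK-52E cells, a rat kidney line of tubular epithelial cells. Each of 4 groups held 3 libraries. The labels name no agent for control cells. TGF-beta1 cells received the profibrotic cytokine TGF-beta1 for 24 h, at 10 µg/ml per the labels, a dose whose unit is in doubt since ng/ml doses are usual. In the other 2 groups this was followed by 48 h with extracellular vesicles (EVs) at 500000000 particles/ml, labelled 2D-EVs for a conventional method and 3D-EVs for a more productive one. These groups are called 2D-EV cells and 3D-EV cells. Library totals were 34385951, 33273281 and 34830269 counts in control cells and 35191827, 35996938 and 36703469 in TGF-beta1 cells. They were 34349927, 35301983 and 32888125 counts in 2D-EV cells and 39754319, 35608995 and 34185568 in 3D-EV cells. A single count stood for 0.0255 to 0.0305 CPM (counts scaled to a common library total), and a count of 0 allowed up to 0.0764 to 0.0916 CPM (3 counts), for counting error only. Means of CPM are given with the SD over the 3 libraries of a group (n = 3), and log2 fold changes with their standard error (SE) from the edgeR fit. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say that they came from separate cultures.

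The comparison of TGF-beta1 cells with control cells addressed which genes the cytokine changed. Col1a1, a chain of type I collagen, rose 2.01-fold (355 ± 14.8 against 177 ± 25.0 CPM), and Fn1, which encodes fibronectin, 1.60-fold (935 ± 29.7 against 585 ± 40.3 CPM). Acta2, the smooth muscle actin of myofibroblasts, rose 1.47-fold (861 against 585 CPM, log2 fold change 0.56, SE 0.03), and Ccn2, a matricellular growth factor, 1.44-fold (4060.1 ± 63.6 against 2823 ± 53.4 CPM). Tgfb1 itself rose 1.64-fold (187 ± 1.00 against 114 ± 8.08 CPM), and Vim, the intermediate filament vimentin, 1.18-fold (2743 ± 16.6 against 2333 ± 15.6 CPM). Across the genome, 3124 of 14184 tested genes changed (1676 rose and 1448 fell, adjusted p below 0.05), 215 of them by a log2 fold change of at least 1 either way. The median absolute log2 fold change of the changed genes was 0.28. Cdh1, the epithelial cadherin, was near the limit of measurement in both groups (0.321 ± 0.186 against 0.627 ± 0.221 CPM, 4 to 30 counts per library) and did not pass (log2 fold change -0.96, adjusted p = 0.241). Havcr1, a marker of tubular injury, held 0 to 8 counts per library and was not tested. Lcn2, a secreted iron-binding protein of injured tubules, fell (7.97 ± 0.207 against 10.2 ± 0.874 CPM, log2 fold change -0.36, adjusted p = 0.0285), a call lost without control replicate 1 (0.0544) or 3 (0.119), or TGF-beta1 replicate 1 (0.0817), 2 (0.0598) or 3 (0.0689).

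**Figure D1:**
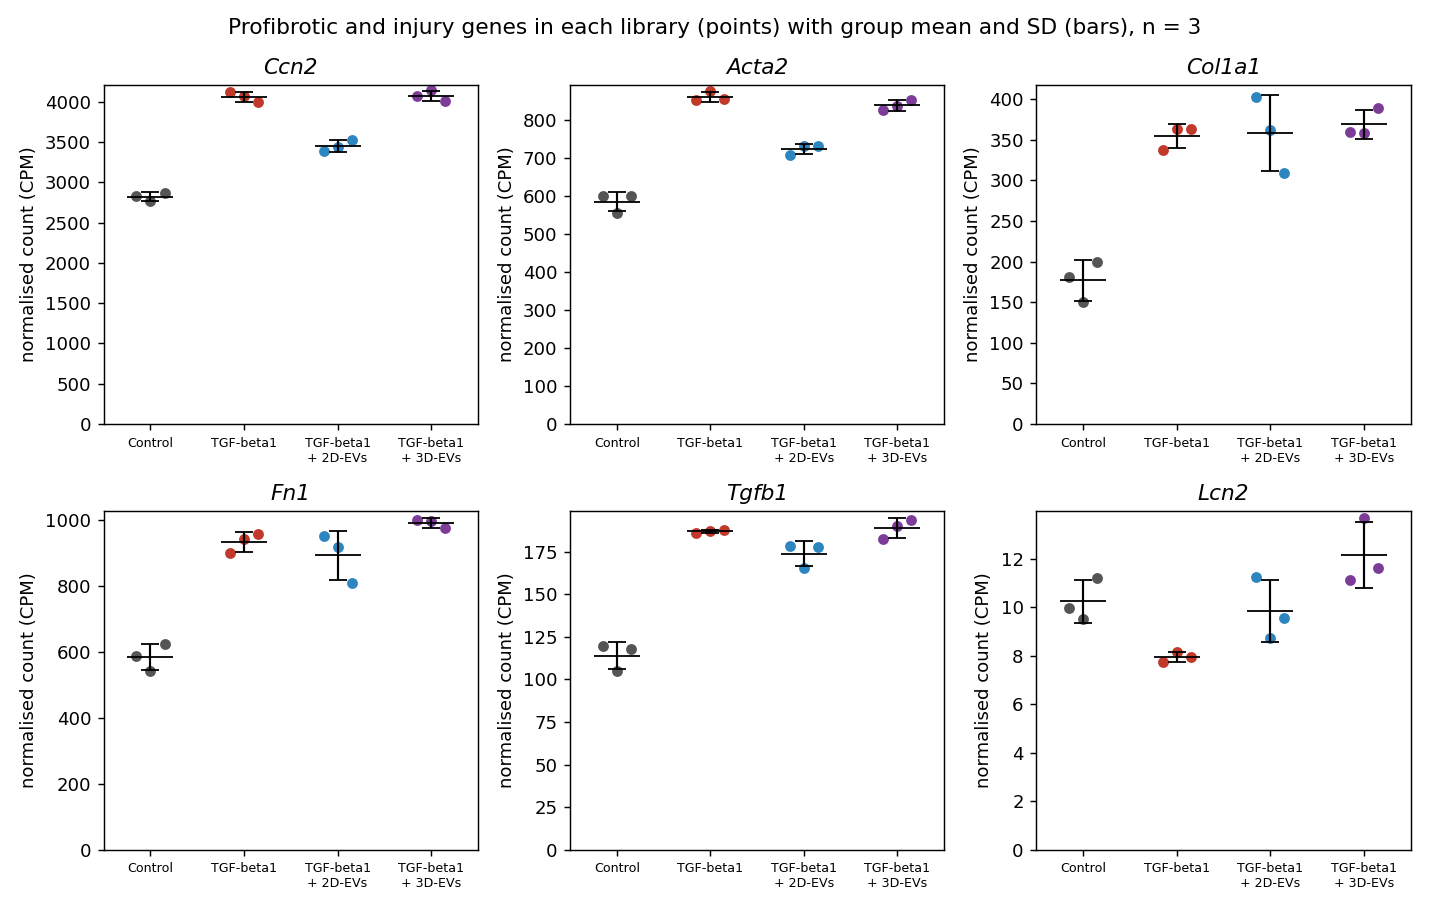
CPM of Ccn2, Acta2, Col1a1, Fn1, Tgfb1 and Lcn2 (y axis, from 0) in the 4 groups (x axis), with a point per library and bars at the mean with SD (n = 3). Ccn2 stood at 4060 CPM after TGF-beta1, 3451 CPM with 2D-EVs and 4072 CPM with 3D-EVs, against 2823 CPM in control cells.

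The largest rises among genes whose libraries did not overlap between the groups were in weakly expressed genes. Ctsw, a protease of cytotoxic lymphocytes, rose 7.48-fold (3.01 ± 0.495 against 0.397 ± 0.197 CPM), and Elf5, an epithelial transcription factor, 5.92-fold (7.28 ± 0.688 against 1.23 ± 0.182 CPM). Ribc2 (4.30 against 0.771 CPM), Birc7 (5.11 against 1.14 CPM), Klk4 (1.29 against 0.314 CPM), Rdh16 (21.4 against 5.36 CPM) and Prdm1 (2.64 against 0.683 CPM) followed. Fbln2, which encodes the matrix protein fibulin-2, rose 3.70-fold from a higher level (164 against 44.2 CPM, SE of log2 0.05). Among the falls, Selenbp1, a selenium-binding protein, dropped from 7.29 to 0.996 CPM (log2 fold change -2.87, SE 0.26) and Pkhd1l1 from 8.29 to 1.23 CPM (-2.75, SE 0.18). Sult1a1, a sulfotransferase (1.02 against 5.68 CPM), Aldh3a1, an aldehyde dehydrogenase (4.16 against 17.0 CPM), and Tst, a sulfurtransferase (2.53 against 9.40 CPM), fell too. Cpz (log2 fold change -1.96) and Rnf112 (-1.94) fell as well. Hsd17b8 fell from 65.7 ± 28.0 to 11.6 ± 3.54 CPM, with a wide spread among control libraries. Its libraries stood at 67.4, 62.3 and 45.2 CPM in 2D-EV cells and at 10.6, 54.1 and 41.0 CPM in 3D-EV cells. It thus also varied widely within a group given TGF-beta1, and its fall is uncertain as a TGF-beta1 response. Values without overlap arise by chance for 10% of genes in comparisons of 3 against 3 libraries. 2789 of the changed genes also met the other criteria for naming (1491 higher, 1298 lower).

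Lists fixed before the data were examined described the groups of genes. Of 34 tested extracellular matrix genes, 21 rose, 5 fell and 8 did not pass. The laminin chains Lamb3 (309 ± 11.8 against 179 ± 2.61 CPM) and Lama3 (138 ± 9.07 against 67.3 ± 1.95 CPM) rose, while Col3a1, type III collagen (98.7 ± 12.2 against 262 ± 40.3 CPM), and Eln, elastin (368 ± 23.1 against 534 ± 64.6 CPM), fell. Adjusted over the list alone, 21 and 5 rose and fell, and the list was higher than other genes (camera adjusted p = 6.0e-11, and adjusted p = 0.0882 with an estimated correlation). Of 31 mesenchymal and contractile genes, 16 rose, 1 fell and 14 did not pass (19 and 2 adjusted over the list alone), with Tagln, an actin-binding protein of smooth muscle, up 1.54-fold (619 ± 14.8 against 403 ± 16.6 CPM) and Mmp2, gelatinase A, down (24.1 against 34.7 CPM). This was the only list whose camera call held with both correlations. For the mesenchymal and contractile list, adjusted p was 3.1e-10, and adjusted p = 0.00218 with an estimated correlation. Of 28 TGF-beta targets and feedback genes, 10 rose, 10 fell and 8 did not pass (10 and 10 adjusted over the list alone). Tgfb1 rose, while Tgfb3 (447 ± 11.5 against 584 ± 6.68 CPM) and Bmp4 (95.5 against 123 CPM) fell. Its median log2 fold change was just below 0 while its mean was 0.09 and its test pointed up. For the TGF-beta targets and feedback list, adjusted p was 0.00141, and adjusted p = 0.128 with an estimated correlation. Of 22 YAP and mechanical targets, 7 rose, 1 fell and 14 did not pass (7 and 1 adjusted over the list alone), among them Tgfb2 (145 against 117 CPM) up and Amotl2, a feedback regulator of YAP, down (log2 fold change -0.14). The list was higher (adjusted p = 0.0145, and adjusted p = 0.235 with an estimated correlation). Across all lists, 22 of 727 genes stood in more than 1 list, Ccn2 and Tgfb2 among the TGF-beta and YAP targets, Snai1 among the TGF-beta and mesenchymal genes.

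Epithelial genes went both ways. Of 19 junction and keratin genes, 4 rose, 4 fell and 11 did not pass (4 and 5 adjusted over the list alone). Krt8, a keratin of simple epithelia (1216 ± 41.6 against 1013 ± 6.96 CPM), and Jup, plakoglobin (log2 fold change 0.25), rose, while the tight junction genes Cgn (48.2 against 67.7 CPM) and Tjp3 (2.66 against 5.75 CPM) fell. For the junction and keratin list, adjusted p was 0.672. Of 16 renal tubule genes, 2 rose, 2 fell and 12 did not pass (3 and 3 adjusted over the list alone). Ggt1, a glutathione-cleaving enzyme of the brush border, rose 1.85-fold (305 ± 10.9 against 165 ± 7.30 CPM) and Atp1b1, a sodium pump subunit, rose by 0.13 (log2). The median of the tubule list was -0.16 and its mean -0.15, although its test pointed up (adjusted p = 0.614). Of 19 tubular injury genes, 7 rose, 3 fell and 9 did not pass (8 and 4 adjusted over the list alone). Spp1, osteopontin (6374 ± 140.5 against 4207 ± 249.7 CPM), and Tnfrsf12a, the TWEAK receptor (243 against 179 CPM), rose, and Anxa1 (1887 against 2136 CPM) fell. The injury list was higher (adjusted p = 0.000237, and adjusted p = 0.0882 with an estimated correlation).

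Of 35 cell cycle genes, 0 rose, 23 fell and 12 did not pass (0 and 27 adjusted over the list alone), with Top2a, a mitotic topoisomerase (189 ± 3.39 against 238 ± 4.57 CPM), and Mki67, the proliferation marker Ki-67 (124 ± 3.21 against 152 ± 6.40 CPM), as examples. For the cell cycle list, adjusted p was 4.7e-11, and adjusted p = 0.0882 with an estimated correlation. Of 26 immediate early genes, 0 rose, 8 fell and 18 did not pass (1 and 8 adjusted over the list alone), among them Spry2, an inhibitor of receptor kinase signalling (49.8 against 62.9 CPM), and Zfp36, which destabilises cytokine mRNAs (123 against 182 CPM). The list was lower (adjusted p = 0.00826, and adjusted p = 0.418 with an estimated correlation). Of 23 p53, arrest and senescence genes, 4 rose, 7 fell and 12 did not pass (4 and 8 adjusted over the list alone), with Gadd45g up (0.29) and the cyclin-dependent kinase inhibitors Cdkn2c (-0.43) and Cdkn1b (-0.21) down. For the p53, arrest and senescence list, adjusted p was 0.0632. Of 28 apoptosis and cell death genes, 7 rose, 6 fell and 15 did not pass (9 and 7 adjusted over the list alone). Ripk3, a necroptosis kinase, rose 1.60-fold (305 ± 15.9 against 190.4 ± 12.1 CPM) and Bcl2l11, a BH3-only killer protein, fell (26.6 against 36.9 CPM). For the apoptosis and cell death list, adjusted p was 0.408, median slightly below 0 and mean 0.02. Of 24 inflammation and NF-kB genes, 5 rose, 5 fell and 14 did not pass (7 and 5 adjusted over the list alone), Tnfaip2 (148 against 109 CPM) and Ptgs2, cyclooxygenase-2 (19.0 against 11.7 CPM), upward and Csf1, the macrophage growth factor (76.0 against 98.9 CPM), downward. For the inflammation and NF-kB list, adjusted p was 0.428. Of 30 interferon response genes, 2 rose, 6 fell and 22 did not pass (2 and 6 adjusted over the list alone), among them Irf1, an interferon-induced transcription factor, down (13.1 against 18.2 CPM). For the interferon response list, adjusted p was 0.111. The interferon list passed without control replicate 3 (adjusted p = 0.0438) or TGF-beta1 replicate 3 (0.0133), the p53 list without control replicate 2 (0.0450), and the immediate early call was lost without control replicate 3 (0.115).

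Of 29 cholesterol synthesis genes, 26 rose, 0 fell and 3 did not pass (26 and 0 adjusted over the list alone), with a median log2 fold change of 0.34. The list as fixed also held fatty acid genes (Fads1, Fads2, Fasn and Scd), so its counts are not of cholesterol synthesis alone. Fasn, fatty acid synthase, was an example of these (384 ± 8.54 against 287 ± 3.99 CPM). For the cholesterol synthesis list, adjusted p was 1.2e-21, and adjusted p = 0.0882 with an estimated correlation. Of 28 fatty acid oxidation genes, 2 rose, 8 fell and 18 did not pass (2 and 8 adjusted over the list alone). Decr1, a mitochondrial reductase (65.1 against 87.9 CPM), and Pdk4, which holds back glucose oxidation (5.87 against 10.8 CPM), fell. For the fatty acid oxidation list, adjusted p was 0.00826, and adjusted p = 0.128 with an estimated correlation. Of 28 glycolysis and hypoxia genes, 9 rose, 1 fell and 18 did not pass (11 and 3 adjusted over the list alone), with Eno2, an enolase (195 against 145 CPM), and Pfkfb4 (log2 fold change 0.57) higher. For the glycolysis and hypoxia list, adjusted p was 0.0206, and adjusted p = 0.235 with an estimated correlation. Of 30 oxidative phosphorylation genes, 2 rose, 1 fell and 27 did not pass (1 and 1 adjusted over the list alone). Cycs, cytochrome c, rose (0.24) and Sdha, a subunit of complex II, fell (-0.16) (adjusted p = 0.567). Of 30 unfolded protein and ATF4 genes, 11 rose, 2 fell and 17 did not pass (12 and 2 adjusted over the list alone), Vldlr (63.5 against 45.4 CPM) up and Psat1, an enzyme of serine synthesis (107 against 140.4 CPM), down. For the unfolded protein and ATF4 list, adjusted p was 0.00818, and adjusted p = 0.418 with an estimated correlation. Of 16 heat shock genes, 8 rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone), led by the small chaperones Hspb8 (159.9 against 120.4 CPM) and Hspb1 (0.24). For the heat shock list, adjusted p was 0.00455, and adjusted p = 0.179 with an estimated correlation. Of 29 lysosome and endocytosis genes, 12 rose, 2 fell and 15 did not pass (14 and 2 adjusted over the list alone). Neu1, lysosomal sialidase, rose 1.79-fold (288 ± 9.24 against 161 ± 9.84 CPM) and Cav1, the coat protein of caveolae, fell (802 against 1134 CPM). For the lysosome and endocytosis list, adjusted p was 0.00818, and adjusted p = 0.377 with an estimated correlation. Of 26 NRF2 and oxidative stress genes, 6 rose, 8 fell and 12 did not pass (9 and 9 adjusted over the list alone). Ftl1, ferritin light chain, rose 1.41-fold (4181 ± 173 against 2973 ± 104 CPM) and Gsta1, a glutathione transferase, fell (7.05 against 12.6 CPM). For the NRF2 and oxidative stress list, adjusted p was 0.672, test upward, mean -0.03. Without control replicate 3 the calls of the unfolded protein list (adjusted p = 0.0536) and the glycolysis list (0.0536) were lost.

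**Figure D2:**
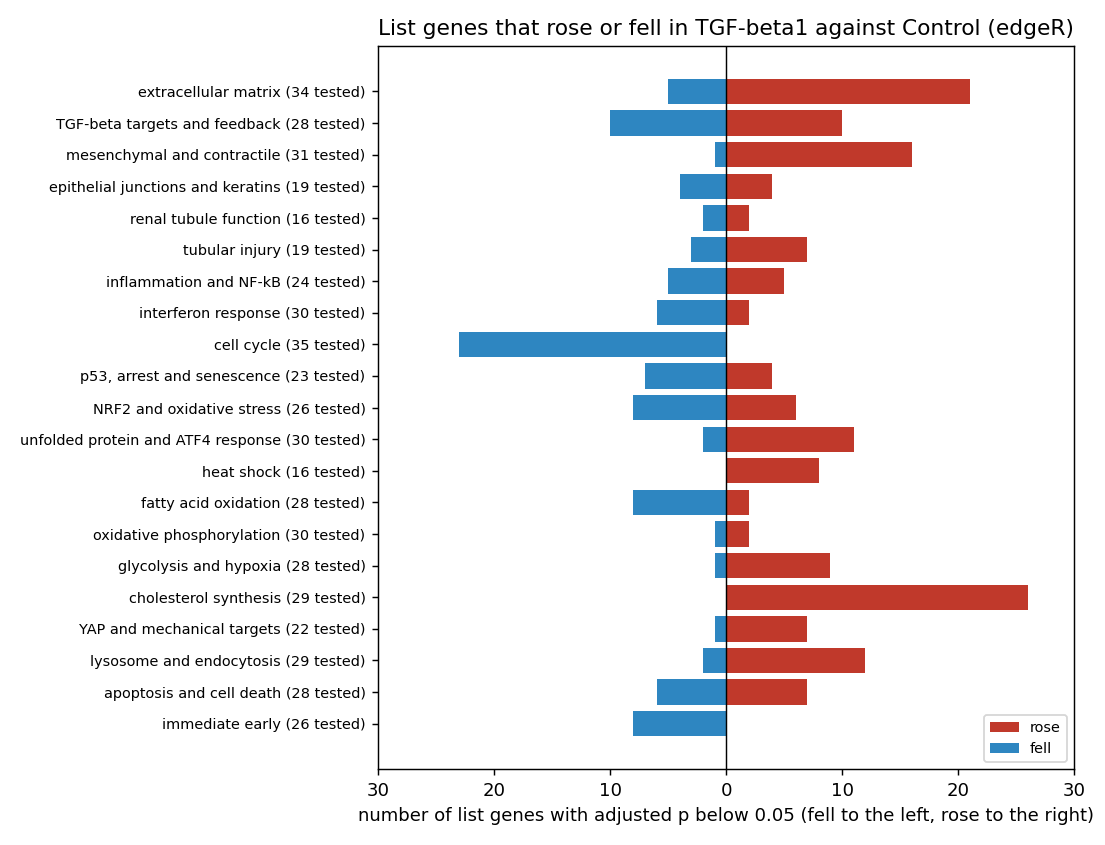
Number of tested genes of each fixed list (y axis) that rose (bars to the right) or fell (bars to the left) in TGF-beta1 against control cells (x axis, genes, adjusted p below 0.05). The bars reach 26 to the right for cholesterol synthesis and 23 to the left for the cell cycle.

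Lists of markers of other cell types did not pass by camera, while by fry the fibroblast and pericyte list was lower (adjusted p = 0.00220) and the immune list higher (adjusted p = 0.0297). Of 6 tested fibroblast and pericyte markers 1 fell, Col14a1, a collagen of fibril-rich tissue (129.8 ± 8.15 against 199 ± 6.59 CPM), and the list did not pass (camera adjusted p = 0.406). Mfap5, a microfibril protein, stood at 551 and 552 CPM. Of 9 mesenchymal stromal cell markers, 2 rose and 1 fell (3 and 1 adjusted over the list alone), the latter Kitlg, the KIT ligand (13.4 against 27.4 CPM). For the mesenchymal stromal cell markers list, adjusted p was 0.854, test downward with a median of 0.17. Of 6 immune markers 1 rose, Cd14, a receptor for bacterial lipopolysaccharide (248 ± 3.78 against 185 ± 7.64 CPM) (adjusted p = 0.535), while Ptprc, C1qa, C1qb, Itgam and Tyrobp held 0 counts in all 12 libraries. Of 5 endothelial markers 1 rose, Egfl7 (13.2 against 9.94 CPM) (adjusted p = 0.854, test upward with a median of -0.14). Only 2 podocyte markers, Nphs1 and Wt1, and 1 erythroid marker, Hba-a2, were tested, too few for a list test. None of the 3 passed in TGF-beta1 against control cells. For RNA quality, none of 13 mitochondrially encoded genes passed in edgeR (adjusted p = 0.673 for the list), and mitochondrial genes took 5.31 to 5.58% of the counts of a library. Of 21 ribosomal protein genes 1 rose, Rplp0 (log2 fold change 0.11; none adjusted over the list alone; list adjusted p = 0.673), a call lost without TGF-beta1 replicate 1 (adjusted p = 0.0686). By DESeq2 and limma-voom, 3200 and 3116 genes changed in TGF-beta1 against control cells. At an unadjusted p below 0.05 edgeR counted 4685 genes, where chance alone gives 709.

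The comparison of 2D-EV cells with TGF-beta1 cells set cells given the conventional vesicles beside cells given TGF-beta1 alone. Since the harvest time of the latter and the presence of TGF-beta1 during the 48 h with EVs are not given, vesicles, time and withdrawal of TGF-beta1 cannot be separated by this comparison alone. Only 4 genes passed in edgeR, all lower with 2D-EVs and all raised by TGF-beta1: Ccn2 stood at 3451 ± 73.2 against 4060.1 ± 63.6 CPM (log2 fold change -0.23, SE 0.03, adjusted p = 0.00238) and Acta2 at 723 ± 12.6 against 861 ± 12.9 CPM (-0.25, SE 0.03, adjusted p = 0.0102). Olr1, a receptor for oxidised low-density lipoprotein, stood at 37.2 ± 1.35 against 53.6 ± 3.14 CPM (-0.53, SE 0.07, adjusted p = 0.0117), and Frmd4a, a scaffold protein of cell polarity, at 24.1 ± 1.18 against 33.5 ± 2.41 CPM (-0.47, SE 0.07, adjusted p = 0.0178). In each of the 4 genes the 3 libraries with 2D-EVs lay below the 3 without, at 0.694 to 0.850 of the TGF-beta1 level. Libraries of 3D-EV cells, given the same times per the labels, all lay above those of 2D-EV cells. The ranges were 4012 to 4139 against 3385 to 3530 CPM (Ccn2), 826 to 853 against 709 to 731 (Acta2), 45.2 to 51.7 against 35.9 to 38.6 (Olr1) and 30.2 to 32.5 against 22.9 to 25.2 (Frmd4a). Ccn2 also passed between the 2 preparations over all genes tested (edgeR adjusted p = 0.00189). For Ccn2 this argues against time or withdrawal alone, if the libraries came from separate cultures. For Acta2 (adjusted p = 0.0698), Olr1 and Frmd4a, which did not pass there, the ranges cannot decide, since the same 2D-EV libraries chose the genes. The matrix protein Thbs1, thrombospondin-1, just missed the threshold (2052 ± 78.3 against 2456 ± 87.0 CPM, log2 fold change -0.26, adjusted p = 0.0570). Other genes of the panel did not pass: Col1a1 (358 ± 46.8 against 355 ± 14.8 CPM, log2 fold change 0.01, adjusted p = 0.987), Fn1 (-0.06, adjusted p = 0.860), Vim (-0.03, 0.884), Tgfb1 (-0.11, 0.659), Cdh1 (-0.12, 0.981) and Lcn2 (0.31, 0.546). At an unadjusted p below 0.05 there were 1007 genes. DESeq2 called 54 and limma-voom 9, among them the 4 with Cald1, F2r, Thbs1 and Edn1. Ccn2 passed without any 1 of the 6 libraries. Acta2 was lost without TGF-beta1 replicate 2 (adjusted p = 0.0614) or 2D-EV replicate 1 (0.0696) or 2 (0.0511). Olr1 was lost without TGF-beta1 replicate 1 (0.0822) or 2 (0.0522) or 2D-EV replicate 1 (0.0669), 2 (0.0778) or 3 (0.0749), and Frmd4a without TGF-beta1 replicate 2 (0.0614) or 3 (0.113) or 2D-EV replicate 1 (0.152), 2 (0.101) or 3 (0.0612).

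As a list, mesenchymal and contractile genes were lower with 2D-EVs. Of 31 mesenchymal and contractile genes 1 fell, Acta2 (8 adjusted over the list alone), with a median log2 fold change of -0.05 (camera adjusted p = 2.5e-07, and adjusted p = 0.00648 with an estimated correlation). Of 28 TGF-beta targets and of 22 YAP targets 1 fell, Ccn2, which stands in both lists (6 and 7 adjusted over the list alone). Camera gave adjusted p = 0.000165 and 2.5e-07 downward, and adjusted p = 0.148 and 0.0625 with an estimated correlation. No immediate early gene passed (2 lower adjusted over the list alone). Maff stood at 20.7 against 26.1 CPM (adjusted p = 0.255), and the list was lower (adjusted p = 0.00819, and adjusted p = 0.518 with an estimated correlation), a call lost without TGF-beta1 replicate 1 (0.490) or 2D-EV replicate 3 (0.200). No NRF2 gene passed, alone or over all genes. Nqo1, a quinone reductase, stood at 156 against 144 CPM (adjusted p = 0.386), and the list was higher (adjusted p = 0.0474, and adjusted p = 0.423 with an estimated correlation). That call was lost without TGF-beta1 replicate 2 (0.0526) or 3 (0.231) or 2D-EV replicate 2 (0.0676) or 3 (0.253). Ribosomal protein genes, an RNA quality list with 0 members passing, were lower (adjusted p = 0.0398, and adjusted p = 0.730 with an estimated correlation; Rpl13 -0.06, Rps23 -0.10), not so without TGF-beta1 replicate 1 (0.933) or 2D-EV replicate 1 (0.503) or 2 (0.207).

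The other lists did not pass with 2D-EVs and none of their members passed in edgeR. Across these 16 response lists the camera adjusted p ran from 0.0907 to 0.603. Extracellular matrix genes had adjusted p = 0.0938 (1 lower adjusted over the list alone, median -0.02, mean 0.01), tubular injury genes 0.0938 (3 lower over the list alone), p53 genes 0.603 (2 lower over the list alone) and apoptosis genes 0.356 (1 lower over the list alone). In the unfolded protein list (0.0907, 2 higher over the list alone), Ddit3, a transcription factor of that response, stood at 41.8 against 34.5 CPM (adjusted p = 0.0961). The 5 other marker lists ran from 0.110 to 0.897, with 2 immune markers lower adjusted over the list alone (Cd14 224 against 248 CPM, adjusted p = 0.237). Median, mean and test differed in sign for the extracellular matrix, p53, unfolded protein, apoptosis, endothelial and mitochondrially encoded lists. Several lists passed when 1 library was left out: without TGF-beta1 replicate 3, interferon (0.000655), oxidative phosphorylation (0.000655), tubular injury (0.0255), fatty acid oxidation (0.0255) and unfolded protein (0.0268), and without replicate 1, extracellular matrix (0.00478) and epithelial junctions (0.0249), and without replicate 2, immune markers (0.0270). Without 2D-EV replicate 1 these were unfolded protein (3.4e-05), epithelial junctions (0.0165) and extracellular matrix (0.0409, and 0.0145 without replicate 2), and without replicate 3 cholesterol (0.0151), heat shock (0.0236) and fatty acid oxidation (0.0405).

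The comparison of 3D-EV cells with TGF-beta1 cells set cells given the more productive preparation beside cells given TGF-beta1 alone, with the same uncertainty over time and TGF-beta1 exposure. No gene passed in edgeR (smallest adjusted p = 0.405, with 1027 genes at an unadjusted p below 0.05). DESeq2, which adjusted over far fewer genes in this comparison, called 21, among them Ctsl, B2m, Csf1 and Icam1, and limma-voom 0. The fibrosis panel stood near its TGF-beta1 level: Ccn2 at 4072 ± 63.7 against 4060.1 ± 63.6 CPM (log2 fold change 0.00, SE 0.03), Acta2 at 838 ± 13.9 against 861 ± 12.9 CPM (-0.04), Fn1 at 991 ± 14.4 against 935 ± 29.7 CPM (0.08) and Col1a1 at 369 ± 17.4 against 355 ± 14.8 CPM (0.05), with adjusted p from 0.782 to 0.986. Vim (0.00, adjusted p = 0.998), Tgfb1 (0.01, 0.977) and Cdh1 (-1.01, 0.774) did not pass either. Lcn2 stood at 12.2 ± 1.36 against 7.97 ± 0.207 CPM (log2 fold change 0.61, SE 0.11, adjusted p = 0.405), and C3, the central complement protein, at 6.19 ± 2.87 against 2.54 ± 0.288 CPM (1.29, SE 0.26, adjusted p = 0.405, and 0.0442 without 3D-EV replicate 3). The count was 1 without TGF-beta1 replicate 2 and 2 without 3D-EV replicate 3.

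The inflammation and NF-kB list was higher with 3D-EVs by camera, with a median log2 fold change of 0.14 (adjusted p = 6.9e-08), a call lost with adjusted p = 0.173 with an estimated correlation and by fry (adjusted p = 0.155). None of its 24 tested genes passed over all genes, while 8 were higher adjusted over the list alone, Lcn2 and C3 first. The list's medians against the mean of the TGF-beta1 libraries were 0.0701, 0.201 and 0.108 in the 3 libraries with 3D-EVs. Lysosome and endocytosis genes were higher by a median of 0.07 (0 passed; 4 higher adjusted over the list alone; adjusted p = 6.9e-08, and adjusted p = 0.314 with an estimated correlation), with the lysosomal protease Ctsl at 2038 ± 74.1 against 1854 ± 49.7 CPM (adjusted p = 0.503) and the cholesterol-binding protein Npc2 at 900.4 against 829 CPM (adjusted p = 0.583). The other 19 response lists did not pass and had no member passing in edgeR (adjusted p = 0.0791 to 0.992), among them extracellular matrix (0.992), TGF-beta targets (0.992) and mesenchymal genes (0.816). Adjusted over the list alone, 2 tubular injury genes were higher and 2 lower, 1 unfolded protein gene (Ddit3, 41.4 against 34.5 CPM) and 1 fatty acid oxidation gene were higher and 1 YAP target was lower. The 6 tested marker lists ran from 0.197 to 0.713. Median, mean and test differed in sign for the extracellular matrix, TGF-beta, mesenchymal, NRF2, YAP, apoptosis and endothelial lists. Lists that passed without 3D-EV replicate 1 were cell cycle (0.00517), oxidative phosphorylation (0.0202), tubular injury (0.0274), interferon (0.0364), YAP targets (0.0388), NRF2 (0.0441) and fatty acid oxidation (0.0441), and without replicate 3, unfolded protein (0.00498) and cholesterol (0.00557). Without TGF-beta1 replicate 3 these were ribosomal protein (0.0112), interferon (0.0144), unfolded protein (0.0187), fatty acid oxidation (0.0278) and cholesterol (0.0278) genes, without replicate 1 oxidative phosphorylation (0.0271) and without replicate 2 mitochondrially encoded genes (0.00205).

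The direct comparison of 3D-EVs with 2D-EVs, the stated aim of the series, gave 1 gene. Ccn2 was higher with 3D-EVs, at 4072 ± 63.7 against 3451 ± 73.2 CPM (log2 fold change 0.24, SE 0.03, 1.18-fold, adjusted p = 0.00189), above in 3 of 3 libraries. Acta2 (838 ± 13.9 against 723 ± 12.6 CPM, 0.21, adjusted p = 0.0698) did not pass. The remaining panel genes had log2 fold changes of 0.15 (Fn1, adjusted p = 0.618), 0.04 (Col1a1, 0.959), 0.03 (Vim, 0.878), 0.12 (Tgfb1, 0.654), -0.89 (Cdh1, 0.831) and 0.30 (Lcn2, 0.618). As a list, mesenchymal and contractile genes were higher with 3D-EVs (median 0.08; 0 passed, 6 higher adjusted over the list alone; adjusted p = 3.3e-06, and adjusted p = 0.00947 with an estimated correlation). Tagln stood at 619.6 ± 10.2 against 543 ± 22.7 CPM (adjusted p = 0.159). TGF-beta targets (1 rose, 3 adjusted over the list alone; adjusted p = 8.9e-05) and YAP targets (1 rose, 4 over the list alone; 0.000417) were higher, with adjusted p = 0.104 and 0.153 with an estimated correlation. So were inflammation genes (0 passed, 1 over the list alone; 3.8e-06), tubular injury genes (0 and 0; 0.000262) and lysosome genes (0 and 0; 4.1e-06), with adjusted p = 0.104, 0.104 and 0.184 with an estimated correlation. Cxcl1, a neutrophil chemokine, stood at 48.3 ± 14.9 against 30.8 ± 2.42 CPM (adjusted p = 0.457, and 0.0170 without 3D-EV replicate 3), and the lysosomal protease Ctsb at 1614 against 1511 CPM (adjusted p = 0.618). Oxidative phosphorylation genes were higher too (0 passed; adjusted p = 0.00936, and adjusted p = 0.668 with an estimated correlation), a call lost without 2D-EV replicate 1 (0.202) or 3D-EV replicate 2 (0.107) or 3 (0.184). In edgeR 978 genes had an unadjusted p below 0.05. DESeq2, which adjusted over far fewer genes here, called 35 and limma-voom 2, and edgeR called 3 without 3D-EV replicate 3.

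The remaining lists did not pass between the preparations and had no member passing. Across these 14 response lists adjusted p ran from 0.0612 to 0.997. In the extracellular matrix list (0.0751) Thbs1 was higher adjusted over the list alone (2313 against 2052 CPM). The 6 tested marker lists ran from 0.200 to 0.915. Adjusted over the list alone, the pericyte marker Cspg4 was lower (3.00 against 4.15 CPM) and Cd14 higher (244 against 224 CPM). Median, mean and test differed in sign for the extracellular matrix, epithelial, renal tubule, unfolded protein, fatty acid oxidation, glycolysis and endothelial lists. Lists that passed without 2D-EV replicate 1 were cholesterol (2.8e-05), immediate early (0.00362), extracellular matrix (0.0411) and unfolded protein (0.0473), and without replicate 2, cell cycle (0.00821) and extracellular matrix (0.00966), and without replicate 3, ribosomal protein (0.000886) and heat shock (0.00683). Without 3D-EV replicate 1 these were ribosomal protein (0.000487), cell cycle (0.0133), heat shock (0.0214) and immediate early genes (0.0223), without replicate 2 extracellular matrix (0.0291) and immediate early genes (0.0291), and without replicate 3 cholesterol genes (0.0275).

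The comparison of 2D-EV cells with control cells addressed how far the vesicle-treated cells stayed from untreated ones. Col1a1 (358 ± 46.8 against 177 ± 25.0 CPM, 2.02-fold), Fn1 (1.53-fold), Tgfb1 (1.52-fold), Acta2 (1.24-fold), Ccn2 (1.22-fold) and Vim (1.15-fold) all rose. Cdh1 (-1.08, adjusted p = 0.208) and Lcn2 (-0.06, 0.785) did not pass. The largest rises were in Ctsw (1.95 against 0.397 CPM), Ribc2, Elf5, Klk4, Kcnh6, Birc7, Anxa10 and Srpx2 (log2 fold change 2.28 down to 1.80), and the largest falls in Selenbp1 (1.44 against 7.29 CPM), Pkhd1l1, Cpz, Serping1, Sult1a1, Aldh3a1, Plagl1 and Mgp (-2.34 to -1.36). Plagl1, a zinc finger factor, fell from a clear level (25.3 ± 1.31 against 69.3 ± 1.57 CPM). In edgeR 2642 genes changed (1489 rose, 1153 fell; 4260 at an unadjusted p below 0.05; 2722 by DESeq2 and 2641 by limma-voom), 148 of them by a log2 fold change of at least 1 either way. Of the lists, cholesterol synthesis (26 of 29 rose, 1.0e-24), extracellular matrix (18 rose and 5 fell of 34, 3.1e-10; Loxl2, a collagen cross-linking enzyme, 294 against 203 CPM) and mesenchymal genes (12 rose and 1 fell of 31, 1.5e-05) were higher by camera adjusted p, and cell cycle genes were lower (25 of 35 fell, 2.9e-14). Adjusted p with an estimated correlation was 0.0793, 0.0904, 0.0207 and 0.0793, and the counts adjusted over the list alone were 26 and 0, 20 and 5, 12 and 1, and 0 and 26.

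Other lists past the threshold in 2D-EV cells against control cells are given with the numbers that rose and fell, the numbers adjusted over the list alone, the camera adjusted p and the adjusted p with an estimated correlation, in that order. Higher lists were unfolded protein (13 rose and 1 fell of 30; 19 and 3 over the list alone; 8.6e-05; 0.239), lysosome (13 rose and 2 fell of 29; 16 and 3 over the list alone; 0.000874; 0.239), tubular injury (9 rose and 2 fell of 19; 9 and 2 over the list alone; 0.00121; 0.0904), glycolysis (10 rose and 0 fell of 28; 10 and 0 over the list alone; 0.00438; 0.181) and heat shock (6 rose and 0 fell of 16; 6 and 0 over the list alone; 0.0168; 0.239), the last lost without control replicate 3 (0.0527) or 2D-EV replicate 3 (0.0659). Vegfa, the endothelial growth factor, was an example of the glycolysis and hypoxia list (112 against 82.0 CPM), and Asns, asparagine synthetase, of the unfolded protein list (log2 fold change 0.30). Lower lists were immediate early (0 rose and 8 fell of 26; 0 and 9 over the list alone; 2.0e-05; 0.239) and p53 (1 rose and 4 fell of 23; 1 and 4 over the list alone; 0.0256; 0.0904). Lists that did not pass were TGF-beta targets (9 rose, 10 fell, adjusted p = 0.0720), fatty acid oxidation (2 and 7, 0.0534), YAP targets (4 and 2, 0.771), NRF2 (7 and 6, 0.159), inflammation (7 and 3, 0.227), interferon (1 and 5, 0.304), epithelial junctions (4 and 5, 0.227), renal tubule (2 and 1, 0.283), oxidative phosphorylation (1 and 1, 0.992) and apoptosis (7 and 5, 0.606). Median, mean and test differed in sign for the TGF-beta, renal tubule, oxidative phosphorylation, YAP, fibroblast, immune and endothelial lists. TGF-beta targets passed without 2D-EV replicate 3 (0.0294), and fatty acid oxidation without control replicate 2 (0.0364) or 2D-EV replicate 1 (0.0327).

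Cells given 3D-EVs also stayed apart from control cells. Col1a1 (369 ± 17.4 against 177 ± 25.0 CPM, 2.08-fold), Fn1 (1.69-fold), Tgfb1 (1.66-fold), Ccn2 (1.44-fold), Acta2 (1.43-fold) and Vim (1.18-fold) rose, and Lcn2 did not pass (0.25, adjusted p = 0.125). Cdh1 fell (0.156 ± 0.0984 against 0.627 ± 0.221 CPM, adjusted p = 0.0268), a call on 2 to 30 counts per library that was lost without control replicate 2 (0.0658) or 3 (0.113) or 3D-EV replicate 1 (0.0833) or 3 (0.108). Ribc2, Ctsw, Elf5, Kcnh6, Birc7, Nppb, Srpx2 and Anxa10 rose the most (log2 fold change 2.60 down to 1.94). Nppb, which encodes a natriuretic peptide, stood at 19.1 ± 2.16 against 4.76 ± 1.07 CPM. Usp4 fell the most (-3.45, SE 0.90), with a wide spread among control libraries (2.96 ± 0.861 against 32.7 ± 24.1 CPM) and an adjusted p of 0.247 by limma-voom. Pkhd1l1, Selenbp1, Sult1a1, Cpz, Rnf112, Aldh3a1 and Rspo1 followed (-2.77 to -1.74). Rspo1, a WNT agonist, stood at 3.25 against 10.9 CPM. In edgeR 3262 genes changed (1731 rose, 1531 fell; 4821 at an unadjusted p below 0.05; 3313 by DESeq2 and 3286 by limma-voom), 200 of them by a log2 fold change of at least 1 either way. Cholesterol synthesis (23 rose and 1 fell of 29, 5.7e-18), extracellular matrix (18 and 5 of 34, 3.1e-11), mesenchymal genes (15 and 1 of 31, 6.1e-10) and lysosome genes (18 and 2 of 29, 3.3e-07; Neu1 303 against 161 CPM) were higher, and cell cycle genes lower (26 of 35 fell, 3.0e-14). Adjusted p with an estimated correlation was 0.0759, 0.0759, 0.00270, 0.106 and 0.0759, with 25 and 1, 19 and 5, 17 and 1, 21 and 2, and 0 and 26 adjusted over the list alone.

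For the other lists past the threshold in 3D-EV cells against control cells the same 4 quantities follow. Higher lists were tubular injury (9 rose and 2 fell of 19; 9 and 2 over the list alone; 4.2e-06; 0.0543; Spp1 6633 against 4207 CPM), unfolded protein (15 rose and 2 fell of 30; 15 and 2 over the list alone; 0.000227; 0.240), TGF-beta targets (9 rose and 9 fell of 28; 12 and 12 over the list alone; 0.000901; 0.106), inflammation (9 rose and 2 fell of 24; 10 and 2 over the list alone; 0.00175; 0.171), heat shock (6 rose and 0 fell of 16; 8 and 0 over the list alone; 0.00175; 0.146) and glycolysis (8 rose and 2 fell of 28; 8 and 2 over the list alone; 0.0115; 0.171). The TGF-beta list pointed up with a median of -0.02 and a mean of 0.11. Ccl2, a monocyte chemokine of the inflammation list, stood at 11.6 ± 4.39 against 3.22 ± 0.383 CPM (log2 fold change 1.84). Lower lists were immediate early (0 rose and 10 fell of 26; 1 and 10 over the list alone; 0.00175; 0.329) and p53 (1 rose and 7 fell of 23; 2 and 7 over the list alone; 0.0314; 0.106), the latter lost without control replicate 1 (0.0577) or 3D-EV replicate 1 (0.0560). Lists that did not pass were fatty acid oxidation (2 rose, 8 fell, adjusted p = 0.0696; 0.0493 without 3D-EV replicate 3), YAP targets (5 and 3, 0.0840; 0.0401 without 3D-EV replicate 3), interferon (1 and 6, 0.214), renal tubule (2 and 2, 0.250), oxidative phosphorylation (1 and 1, 0.260), apoptosis (7 and 4, 0.324), NRF2 (9 and 8, 0.324) and epithelial junctions (4 and 5, 0.496). Among RNA quality genes, Mt-nd4 (5131 against 4771 CPM) and Mt-cyb rose, Mt-cyb not without control replicate 2 (0.115) or 3D-EV replicate 2 (0.0925) or 3 (0.101), and the list did not pass (adjusted p = 0.549). The 6 tested marker lists ran from 0.549 to 0.970 in adjusted p, and all 6 stood at 0.788 in 2D-EV cells against control cells. In 3D-EV cells median, mean and test also differed in sign for the renal tubule, NRF2 and endothelial lists.

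TGF-beta1-changed genes that were moved back in cells given vesicles were counted against simulated libraries with no vesicle effect, because both comparisons share the 3 TGF-beta1 libraries. Of the 3124 genes, 4 were moved back in 2D-EV cells (Ccn2, Acta2, Olr1 and Frmd4a, all raised by TGF-beta1) and 0 moved further in edgeR. Here and below, moved back or further by EVs names the groups compared and not a tested cause. 50 simulated data sets gave a mean of 0.18 and at most 1 gene back, while DESeq2 counted 48 back and limma-voom 9. With 3D-EVs 0 genes moved back and 0 further in edgeR, beside a simulated mean of 0.16 and at most 2 back. By DESeq2, which adjusted over far fewer genes with 3D-EVs, the counts were 12 back and 4 further, and limma-voom called 0 genes in that comparison. The share of the 3124 genes with a sign opposite to the TGF-beta1 change was 74.8% with 2D-EVs, against 62.3% (at most 64.4%) in the simulations, and 63.5% with 3D-EVs, which 4 of 50 simulations reached. Across genes, which are not independent replicates, the change with EVs correlated with the TGF-beta1 change by -0.433 with 2D-EVs and -0.380 with 3D-EVs, beyond the simulated extremes of -0.314 and -0.324, and the covariances were -0.0611 and -0.0494 (simulated extremes -0.0391 and -0.0380). Genes at an unadjusted p below 0.05 numbered 1007 and 1027, with at most 742 and 714 in the simulations. Other splits of the same libraries reached 1102 and 1064. The simulations drew genes independently, so their extremes may be too narrow, and values beyond them do not establish an EV effect. Of the genes raised by TGF-beta1, 1236 were also higher in 2D-EV cells than in control cells and 1335 in 3D-EV cells. Of those lowered, 924 and 1075 were also lower, and 0 were opposite among all genes that edgeR called in both comparisons. These overlaps share the control libraries on which the genes were chosen, so they are no measure of persistence. Without TGF-beta1 replicate 2 the number moved back was 2 for 2D-EVs and 1 for 3D-EVs, and for 2D-EVs it was 1 without 2D-EV replicate 1 or 2 and 2 without replicate 3.

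A TGF-beta1 score per library, the mean log2 CPM of raised genes less that of lowered genes, set to 0 in control cells, was 0.790 ± 0.0122 in TGF-beta1 cells, 0.634 ± 0.0245 in 2D-EV cells and 0.693 ± 0.0207 in 3D-EV cells (SD, n = 3). The genes of the score were chosen on the control and TGF-beta1 libraries themselves, so its distance between TGF-beta1 cells and EV cells is not independent evidence of an EV effect. It was 80.3% of the TGF-beta1 score with 2D-EVs and 87.7% with 3D-EVs. Simulations with no vesicle effect gave 88.5 to 91.6% and 88.9 to 91.9%, and -0.0212 to 0.0167 for 3D-EVs less 2D-EVs. These drew genes independently and had a TGF-beta1 score of 1.01, so they are approximate. The score was higher with 3D-EVs than with 2D-EVs by 0.0591, all 3 libraries above all 3, with an exact two-sided permutation p = 0.1, the smallest that 20 assignments allow. Between the vesicle groups, the 1676 TGF-beta1-raised genes were higher with 3D-EVs by a median log2 fold change of 0.02, 63.3% of them upward (camera p = 6.8e-05, and p = 0.000406 with an estimated correlation). The 1448 TGF-beta1-lowered genes were lower with 3D-EVs by a median of -0.02 (camera p = 0.00148, and p = 0.0606 with an estimated correlation; 0.0524 without 3D-EV replicate 2). Across 14184 genes, which are not independent replicates, the 2D-EV and 3D-EV changes against TGF-beta1 correlated with r = 0.465 (rho = 0.441), where simulations with no vesicle effect gave 0.452 to 0.566 from the shared libraries alone. Their covariance was 0.0469 against a simulated 0.0302 (at most 0.0399), with genes drawn independently. Leaving out 1 library moved r between 0.325 and 0.623.

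**Figure D3:**
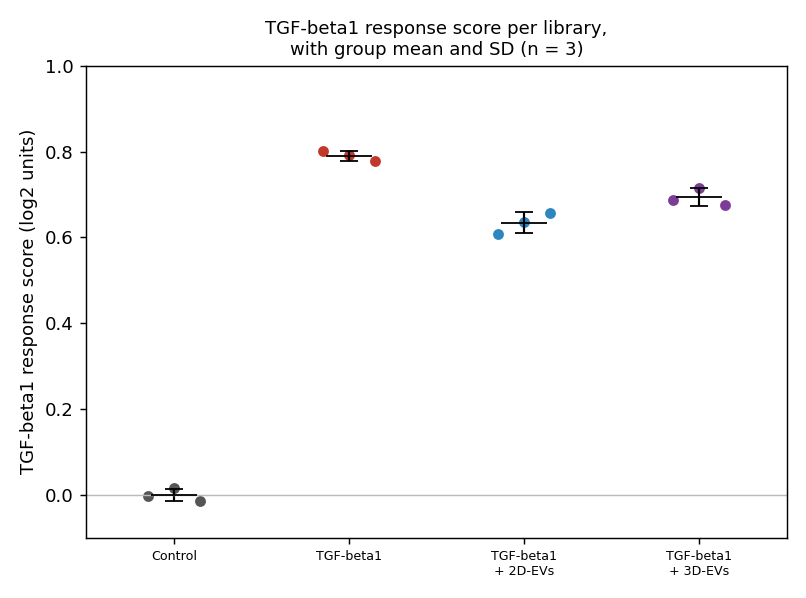
TGF-beta1 score per library (y axis, log2 units, control mean at 0) in the 4 groups (x axis), with a point per library and bars at the mean with SD (n = 3). The 3 libraries with 2D-EVs lie between 0.609 and 0.658 and those with 3D-EVs between 0.676 and 0.716, below the TGF-beta1 libraries at 0.777 to 0.801.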

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

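The tests of neighbouring genes and of immune cell transcripts, the thinned libraries and the fit without genes varying over 5-fold within a group were chosen only after the result was seen. The response to 3D-EVs differed from that to 2D-EVs, by a test of the difference itself, in 3 results that kept the call with an estimated correlation where one applied. The TGF-beta, YAP, inflammation, tubular injury, lysosome and oxidative phosphorylation lists and the TGF-beta1-lowered genes also differed by camera and lost the call with it. Ccn2 was higher with 3D-EVs by 0.24 (log2), higher in 3 of 3 libraries. The mesenchymal and contractile list was higher by a median of 0.0779 (camera adjusted p = 3.3e-06, and adjusted p = 0.00947 with an estimated correlation). The TGF-beta1-raised genes were higher by a median of 0.0202 (camera p = 6.8e-05 and p = 0.000406 with an estimated correlation), 63.3% of them upward. The 10 possible splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3124 genes for TGF-beta1 against control cells, 2642 for 2D-EV and 3262 for 3D-EV against control cells, where the highest other split gave 1 gene in each, so that 1 of the 10 splits reached the real count. For 2D-EV against TGF-beta1 cells the real split gave 4 genes and the highest other 1, again 1 split of 10, and at an unadjusted p below 0.05 another split had 1102 genes against the real 1007. For 3D-EV against TGF-beta1 cells the real split gave 0 genes and the highest other 1, so that all 10 splits reached it. At an unadjusted p below 0.05 edgeR had 1027 genes, and another split had 1064. DESeq2, adjusting over far fewer genes, called 21 there and limma-voom 0. For 3D-EV against 2D-EV cells the real split gave 1 gene and the highest other 2, with 2 splits of 10 reaching the real count. At an unadjusted p below 0.05 these had 978 genes in the real split and 1186 in another.

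With 2D-EVs, Ccn2, Acta2, Olr1 and Frmd4a were lower than after TGF-beta1 alone, with a median log2 fold change of -0.36. With every library thinned to the smallest total the median was -0.364 and 4 of 4 genes were still called. Thinning keeps proportions, and the fit already scaled for totals. This outcome was largely set in advance and does not decide on library size. The 100 most abundant genes that TGF-beta1 did not change had a median of -0.0112 (SE 0.0062). The TMM scaling already sets abundant genes near 0, so this median cannot decide whether a few genes took most of the counts. The 10 most abundant genes of a library took a mean of 6.79% of counts in TGF-beta1 cells and 6.75% in 2D-EV cells, so these did not take most. What stays open is whether the 3 libraries per group were separate cultures, which the labels do not say. Time in culture or TGF-beta1 exposure may have differed with the EVs, since the harvest time of TGF-beta1 cells is not given. As the only cause of the fall of Ccn2 this is argued against by 3D-EV cells, given the same times per the labels, if the libraries were separate cultures. Ccn2 was higher with 3D-EVs than with 2D-EVs by 0.24 (log2, edgeR adjusted p = 0.00189 over all genes). Libraries of 3D-EV cells also lay above those of 2D-EV cells in Acta2 (0.21, adjusted p = 0.0698), Olr1 and Frmd4a, which did not pass. For these 3 genes the comparison cannot decide, since the 2D-EV libraries also chose them. The calls rest on few libraries: Acta2 was lost without TGF-beta1 replicate 2 (adjusted p = 0.0614) or 2D-EV replicate 1 (0.0696) or 2 (0.0511), Olr1 without any library but TGF-beta1 replicate 3 (0.0822, 0.0522, 0.0669, 0.0778 and 0.0749) and Frmd4a without any but TGF-beta1 replicate 1 (0.0614, 0.113, 0.152, 0.101 and 0.0612), each list in the order TGF-beta1 then 2D-EV replicates, so an effect of the 2D-EVs remains a hypothesis found and tested on the same data.

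In 3D-EV cells, inflammation and NF-kB genes were higher than after TGF-beta1 alone by a median of 0.14 (camera adjusted p = 6.9e-08; adjusted p = 0.173 with an estimated correlation, and 0.155 by fry). With every library thinned to the smallest total the median was 0.144, an outcome largely set in advance, since thinning keeps proportions. It does not decide on library size. The summed counts of Lyz2 and Cd74, abundant in myeloid and antigen-presenting cells, changed by -14 per library on average (95% interval -34.7 to 6.69, n = 3 each). Lcn2, C3 and Cxcl1 gained 153, 133 and 669. The pair held few counts (means of 19.3 with 3D-EVs and 33.3 without). It speaks only to reads from cells that carry these genes and leaves other immune cells open. Among other tested immune markers, Cd68 (3.84 against 3.19 CPM) and Cd3e (0.474 against 0.442 CPM) were higher with 3D-EVs. Cd14 (244 against 248 CPM) and Fcer1g (146 against 147 CPM) were slightly lower. None of these passed in edgeR, so their directions do not decide on reads from immune cells. Other immune markers at 0 in all 12 libraries were not used for this, since Epcam and Gnai1 were at 0 too and reads of some genes may have been lost in counting. What stays open is whether the genes moved as a coordinated group in a few cultures, since the call was lost with an estimated correlation, and whether time or TGF-beta1 exposure differed with the EVs, and a response of the cells to 3D-EVs remains a hypothesis found and tested on the same libraries.

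Within groups, 46 of 12162 genes with a mean of at least 1 CPM varied over 5-fold between libraries, among them Usp4 (9.33-fold), Manf (15.8-fold), Klf6 (5.42-fold) and Foxm1 (31.7-fold). Mterf2 and Tmem263 ran opposite to each other over the 12 libraries (r = -0.998, across 12 libraries of 4 groups), with Mterf2 between 4.95 and 129 CPM and a nearly constant sum (151 ± 3.23 CPM, SD, n = 12). Of the 28 with a place in the reference gene order, 10 (35.7%) had a neighbouring gene with r below -0.8. Among matched genes these were 9 of 523 (1.72%, Fisher's exact test p = 1.4e-09). The sum was not constant in every such pair (80.3 to 153 CPM for Slc35b2 and Nfkbie), and Mterf2 and Tmem263 were counted each for the other. Only 60.9% of the 46 had a place, under the 80% set for such a check, which is therefore void, and reads shared between neighbouring genes cannot be told apart from other causes for these genes. No biological explanation was tested.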

How the results depend on the processing

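The thinned libraries and the fit without genes varying over 5-fold within a group were chosen after the data were seen. No result reversed under any alternative run for it, and scaling moved the median of all genes by at most 0.0023 (log2). With DESeq2 size factors, the stricter filter and thinning, the 6 counts of changed genes and the genes moved back or further stayed within 1.5 times their value. Changed genes with an absolute log2 fold change of at least 1 numbered 215 for TGF-beta1, 148 for 2D-EV and 200 for 3D-EV against control cells, fewer by construction, and 0 for 2D-EV against TGF-beta1 and for 3D-EV against 2D-EV cells, with 0 genes moved back by 2D-EVs. For 2D-EV against TGF-beta1 cells edgeR gave 4 genes, 14 with no filter (2 higher), 7 with the 6 libraries alone (2 higher and 5 lower, 3 of the 4 among them) and 9 without the varying genes, DESeq2 54 (16 higher and 38 lower) and limma-voom 9. Genes moved back by 2D-EVs numbered 12 with no filter, 48 by DESeq2, 9 by limma-voom and 9 without the varying genes. For 3D-EV against TGF-beta1 cells DESeq2 gave 21, with 12 moved back and 4 further, where edgeR gave 0 (1027 at an unadjusted p below 0.05) and limma-voom 0. For 3D-EV against 2D-EV cells edgeR gave 1, 8 with no filter, 2 with the 6 libraries alone and 2 without the varying genes, DESeq2 35 and limma-voom 2. Apart from the threshold on the fold, the cause was not tested. DESeq2 gave no adjusted p for 15688 of 19266 genes in 3D-EV against TGF-beta1 cells, and for 17929 in 3D-EV against 2D-EV cells. Its 21 and 35 calls were thus adjusted over far fewer genes than the 14184 of edgeR and are not like counts. At an unadjusted p below 0.05 it had 989 and 917 genes, fewer than the 1027 and 978 of edgeR. A block on the replicate number gave a correlation of the EV responses of 0.473 and 2858, 4, 0, 2, 2362 and 2957 genes (TGF-beta1 against control, 2D-EV and 3D-EV against TGF-beta1, 3D-EV against 2D-EV, 2D-EV and 3D-EV against control), and for 2D-EV against TGF-beta1 cells it ended the list calls of NRF2 (adjusted p = 0.0547) and ribosomal protein genes (0.0515). The NRF2 call there was also lost with DESeq2 size factors (0.0506) and thinning (0.0540). By fry, 3 list calls were lost there (NRF2 0.276, immediate early 0.591, ribosomal protein 0.716), both of 3D-EV against TGF-beta1 cells (inflammation and lysosome, 0.155), and 6 of 3D-EV against 2D-EV cells (TGF-beta and tubular injury 0.0551, inflammation and YAP 0.0690, lysosome 0.106, oxidative phosphorylation 0.677). Against control cells fry added 4 calls and lost 1 (immediate early, 0.0682) for TGF-beta1, and added 6 for 2D-EV and 5 for 3D-EV. Leaving out 1 library gave 2419 to 2555 for TGF-beta1 against control cells, 1 to 3 for 2D-EV and 0 to 2 for 3D-EV against TGF-beta1 cells, 1 to 3 for 3D-EV against 2D-EV cells, 2006 to 2311 and 2408 to 2679 for 2D-EV and 3D-EV against control cells, 1 to 5 moved back and 0 to 0 further by 2D-EVs, and 0 to 1 back and 0 to 0 further by 3D-EVs. The 4 genes for 2D-EV against TGF-beta1 cells, all of them moved back, became 2 without TGF-beta1 replicate 2 (1 of the 4, lower, and another gene, higher), 2 of the 4 without 2D-EV replicate 3 and 1 of the 4 without 2D-EV replicate 1 or 2. The 0 genes for 3D-EV became 1 without TGF-beta1 replicate 2 (moved back) and 2 without 3D-EV replicate 3, and the 1 gene between the EVs became 3 without 3D-EV replicate 3. It moved the camera p between 1.4e-05 and 0.00166 for TGF-beta1-raised genes and between 0.000336 and 0.0524 (without 3D-EV replicate 2) for TGF-beta1-lowered genes in 3D-EV against 2D-EV cells, which was 0.0606 with an estimated correlation, and the correlation of EV responses between 0.325 (without 3D-EV replicate 3) and 0.623 (without TGF-beta1 replicate 3). Single genes were not followed under the fold threshold, by which Ccn2, Acta2, Fn1 and Vim lose their calls by construction, or with the 6 libraries alone. Under the other alternatives, 13 of 99 named genes called lost the call in some in TGF-beta1, 7 of 94 in 2D-EV and 19 of 103 in 3D-EV against control cells. In 2D-EV against TGF-beta1 cells 3 of 4 did and Ccn2 did not. Depth limits the genes near the floor, such as Cdh1 and Havcr1. Averaged over genes, the spread between libraries was above counting error. With 200 changed genes, 1.2-fold changes were recovered in 23.6 to 29.2% of simulated cases, and recovery may be lower where few genes change.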

Other observations

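Some genes common in kidney epithelium had no usable counts, a measured fact that bears on the epithelial list. Krt18, the usual partner of the keratin Krt8, held 0 counts in 11 libraries and 5 in a single 3D-EV library, beside Krt8 at 1216 CPM in TGF-beta1 cells. A count of 0 allows up to 0.0764 to 0.0916 CPM for counting error only. Reads of some genes may have been lost in counting, so this sets no limit on the expression of Krt18. Epcam, an epithelial adhesion molecule, and Gnai1, a G protein subunit, held 0 counts in all 12 libraries, and Rps6, an abundant ribosomal protein gene in most cells, 22 counts in total. These genes were chosen after their values were seen.

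Among the markers, Mfap5 stood at 551, 552, 544 and 576 CPM in control, TGF-beta1, 2D-EV and 3D-EV cells, Alcam, an adhesion molecule also found on stromal cells, at 158, 150.3, 158 and 161 CPM, and Fcer1g, an adaptor of immune receptors, at 155, 147, 152 and 146 CPM. Cd14 stood at 185, 248, 224 and 244 CPM.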
